A study of Rattus norvegicus with 24 samples.

How the data were processed

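RNA of tissue labelled as forebrain, from 24 male F344 rats, was hybridised to Affymetrix rat expression arrays, 1 array per rat. In each of 6 groups 4 rats were given vehicle or 5, 20, 50, 200 or 500 mg/kg D-serine once and killed 96 h later. Groups were taken from the labels, which name a separate animal for every array, so the replicates are biological and unpaired; the replicate numbers only name arrays. A small piece of forebrain per rat was used for total RNA, per the labels' protocols, which do not say how the pieces were dissected. Animal numbers in the labels run from vehicle through 500, 200, 50 and 20 to 5 mg/kg, so that any order of handling that followed them goes with the dose.

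The deposited values are intensity, 1 signal per probe set on a linear scale. The signals came from GCOS, Affymetrix's array software, per the submitters' processing notes; its version, settings, scaling target and detection calls are not given in the sources used here. Of the probe sets in the table, 57 were Affymetrix controls. The deposited intensity was not on a common scale. The arrays' medians of log2(intensity + 16) spanned 0.73, more than the 0.5 set beforehand as the limit for values taken as normalized, so quantile normalization was applied by the rule fixed before the data were examined. No value column was left without a sample, and 0 pairs of arrays held identical values. Scan dates, labelling batches and the order of hybridisation were not used here, so no batch could be tested.

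Quantile normalized intensities were taken as log2(intensity + 16), so a fold change is on that scale and understates the change of dim probe sets. Control probe sets and the 40% of probe sets with the lowest mean over all arrays were left out, which left 18625. Gene names came from the platform annotation, in which 20832 probe sets carried 1 gene symbol, 436 several and 9831 none. Symbols were brought up to date through the Entrez ID for 20764, through the accession for 2 and kept for 66, against the RefSeq gene table of the GRCr8 assembly, which was used for names only, so no coordinates are given. A probe set with several symbols names no gene. At the gene level each of 10205 genes was represented by its probe set with the highest mean, and other probe sets are mentioned where they disagree. Counts of genes keep the p adjusted over all probe sets, while the alternative with 1 probe set per gene was fitted and adjusted over genes alone.

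All 24 arrays entered 1 linear model of 6 group means in limma 3.58.1 (R 4.3.3), with moderated tests, an intensity trend in the prior variance and Benjamini-Hochberg adjustment within each comparison. A probe set or gene is said to have risen, fallen or passed where its adjusted p is under 0.05. Each dose was compared with vehicle, all groups were compared by an F test of the 5 differences, the slope over dose rank was tested in a model with an intercept, and 500 was compared with 200 mg/kg. Errors of log2 differences are standard errors of the fit, and those of array measures are SD. Because the 5 comparisons with vehicle share the 4 vehicle arrays, their overlap is set beside simulations of unchanged groups (100 for correlations, 50 for shared calls). It is also set beside the overlap of independent lists, and both are given again with the vehicle arrays split into pairs.

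Gene lists for cell types, brain regions and processes that fit forebrain and a glutamate receptor agonist, 39 in all, were written before the data were examined. Of these, 36 had at least 4 measured members and were tested with limma's camera with a preset correlation of 0.01. Each call is set beside camera with an estimated correlation, which called 0 lists in any comparison of all 24 arrays, and beside limma's fry, given as a range where it called 0 lists. Fry tests whether members move one way on balance and, with all 24 arrays, called 3 lists at 5 mg/kg, 1 at 20 mg/kg and 0 elsewhere. Genes named in the text follow a rule written before the data were examined: in each comparison the 12 largest rises and 12 largest falls among genes that passed, the 10 smallest p values where fewer than 10 genes passed, the 4 members with the smallest p of each list that passed, and 17 genes of D-serine handling, NMDA receptors, activity, glia, choroid plexus and blood whatever their values. Any gene named outside the rule is said to have been chosen after its values were seen. RNA quality was measured as the log2 ratio of the 3' to the 5' control probe set of beta-actin and Gapdh on each array. Each dose group was compared with vehicle by an exact two-sided permutation test, which with 4 against 4 arrays cannot give a p below 0.0286. The hexokinase control, looked at in addition, had a smallest exact permutation p of 0.0857 (adjusted p = 0.357).

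The limma and camera steps were tested on simulated values of probe sets that varied independently. Normalization, filtering and the choice of probe sets were not part of that test. With 200 of 18625 probe sets changed in a simulated comparison of 500 mg/kg against vehicle, 40% of those changed by 0.5 on the log2 scale and 88% of those changed by 1 were recovered with 5 false calls, a simulated unchanged 5 mg/kg group gave 0 calls in limma, and a shifted list was called with 0 others. Since the simulated genes were uncorrelated, the list result does not carry over to lists whose members go together. Striatal markers, for instance, had an estimated correlation of 0.88. For arrays, the number of replicates limits the precision.

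Alternatives fixed before the data were examined were no filter and a filter of 60%, median centring, pseudocounts of 1 and 64, moderation without a trend or with robust moderation, array weights, 1 probe set per gene, only the 8 arrays of both groups, other scales of the dose, the treated groups without vehicle, and leaving out each array in turn. Quantile normalization had been listed as an alternative and became the main setting. Chosen after the data were seen were the values as deposited, median centring for the lists, the Gapdh ratio as a covariate, the comparisons between dose groups other than 500 with 200 mg/kg, lists of cerebellar and forebrain genes used on a single array, and the split of the vehicle arrays for shared calls. The shuffles of the RNA ratio were first run in a larger number and then lowered to 100 after that result was seen, to keep to a limit on repeated fits.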

Results

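Gene expression in tissue labelled as forebrain was measured in adult male F344 rats 96 h after a single dose of D-serine. This amino acid acts as co-agonist of the NMDA type glutamate receptor. Rats received 0 (vehicle), 5, 20, 50, 200 or 500 mg/kg, with 4 rats in each of the 6 groups and 1 Affymetrix rat expression array per rat. The study asked which transcripts differed from vehicle at each dose. Intensities of all probe sets were read on each of the 24 arrays, and the median intensity of an array ran from 55.8 to 103.65. With 4 arrays per group, the median standard error of a log2 difference from vehicle was 0.14.

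Of the signs of RNA quality on the arrays, the beta-actin and Gapdh ratios differed between dose groups, and the hexokinase ratio did not detectably. The log2 ratio of 3' to 5' signal of the beta-actin control probe sets, which is higher where the labelled RNA is shorter, was 2.56 ± 0.19 (SD, n = 4) in vehicle, 2.46 ± 0.15 at 200 mg/kg and 2.51 ± 0.22 at 500 mg/kg. It was 1.69 ± 0.11 at 5 mg/kg, 1.60 ± 0.18 at 20 mg/kg and 1.87 ± 0.08 at 50 mg/kg, and in each of these 3 groups all 4 arrays lay below all 4 vehicle arrays (exact two-sided permutation test, p = 0.0286, the smallest it can give, adjusted p = 0.0476 over 5 comparisons). The Gapdh control probe sets gave 0.83 ± 0.06 (SD, n = 4) in vehicle and 0.19 ± 0.07, 0.18 ± 0.04 and 0.34 ± 0.17 at 5, 20 and 50 mg/kg (exact permutation p = 0.0286 for each, adjusted p = 0.0476). At 200 and 500 mg/kg the Gapdh ratios were 0.60 ± 0.21 (exact permutation p = 0.0857) and 0.75 ± 0.14 (exact permutation p = 0.371). The hexokinase control probe sets gave 2.25 ± 0.53 in vehicle and 1.69 ± 0.38, 1.77 ± 0.13 and 2.23 ± 0.11 at 5, 20 and 50 mg/kg. Their exact permutation p values were 0.143, 0.0857 and 0.971. At 200 and 500 mg/kg this ratio was 2.46 ± 0.45 and 2.38 ± 0.50. The array of 500 mg/kg replicate 4 also stood apart in expression, with a median correlation of 0.855 with the other arrays. On it the neuronal genes Nrgn and Camk2a read -4.81 and -4.10 log2 units from the mean of the other 3 arrays of its group, and cerebellar markers such as Gabra6 read 5.80.

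**Figure D1:**
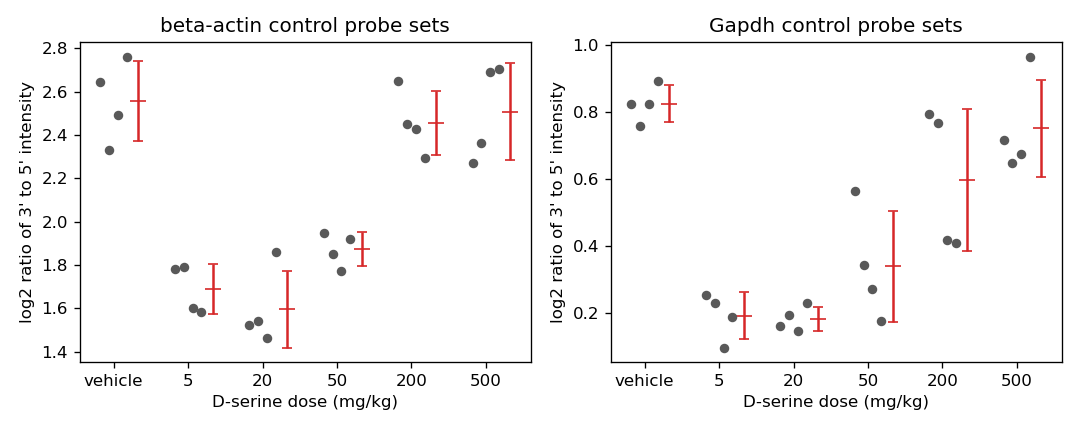
Log2 ratio of 3' to 5' intensity of the beta-actin (left) and Gapdh (right) control probe sets against D-serine dose in mg/kg; points are single arrays, and horizontal marks with bars are the mean ± SD of 4 arrays. The 5, 20 and 50 mg/kg arrays have lower ratios than the vehicle arrays, with beta-actin means of 1.69, 1.60 and 1.87 against 2.56.

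At 5 mg/kg, the largest rises over vehicle included Syt1, Svop and Tbr1. Syt1, the calcium sensor of synaptic vesicle release, rose by 1.26 ± 0.30 on the log2 scale (SE, n = 4 arrays per group, limma adjusted p = 0.0137), which is 2.40-fold. Svop, a synaptic vesicle membrane protein, rose by 1.11 ± 0.16 (adjusted p = 0.00037), and Sh3gl2, the endophilin of vesicle endocytosis, by 0.93 ± 0.20 (adjusted p = 0.00752). Tbr1, a transcription factor of cortical glutamatergic neurons, rose by 1.11 ± 0.25 (adjusted p = 0.00931). Its vehicle arrays read 4.52 to 5.99, at or below about the mean of 5.98 under which probe sets were left out, so it was dim there. The largest falls were Col15a1, a basement membrane collagen, at -0.98 ± 0.18 (adjusted p = 0.00271), and Hipk2, a nuclear protein kinase, at -0.97 ± 0.18 (adjusted p = 0.00249). The other genes with the largest rises were Rasgrp1, a Ras exchange factor, at 1.22, Nsmce4a at 1.21, the actin-bundling gene Fscn1 at 1.03, Cnbd2 at 0.96, Fxyd6 at 0.90, and Frrs1l, Necab1 and Akirin2, each at 0.89. Other falls were the endocytic adaptor Ston2 at -0.95, Nckap5l at -0.80, the lipid kinase Pik3c2b at -0.79, the small heat shock protein gene Hspb1 at -0.76, Rorb and Zfp347 at -0.71, the citron kinase gene Cit at -0.70, Tmed5 at -0.68 and Pnma8b at -0.67. Kif1a, a motor that carries synaptic vesicle precursors, fell by 0.76, while its other probe set read 0.23, and the other probe set of Cnbd2 read -0.02. The synaptic vesicle list as a whole had a median of 0.02 with 7 of 14 genes above vehicle (camera adjusted p = 0.891).

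Over all probe sets, 1028 of 18625 differed from vehicle at 5 mg/kg in limma after Benjamini-Hochberg adjustment, 705 higher and 323 lower, and among 10205 genes taken at 1 probe set each, 187 were higher and 144 lower with the p adjusted over all 18625 probe sets. At an unadjusted p under 0.05 there were 3515 probe sets, where chance alone gives about 931. The share of higher calls was 68.6%, against 82.5% with each array centred on its median, and with the values as deposited 1031 were higher and 10 lower. These calls stood beside the lower 3' to 5' ratios of this group. With the Gapdh ratio as a covariate, chosen after the data were seen, 0 probe sets passed in limma and 1235 had an unadjusted p under 0.05. Syt1 then read -0.64, Rasgrp1 -0.50, Necab1 -0.17 and Pik3c2b 0.07. All fits with this covariate kept 500 mg/kg replicate 4, which stood apart in expression and had the highest Gapdh ratio of its group, 0.97. The covariate was not fitted without that array, so how far these values rest on it was not tested. Over the probe sets that passed at 5 or 20 mg/kg, the median change at 5 mg/kg in the called direction was 0.13 with the covariate against 0.44 without it. The count was 1668 without 500 mg/kg replicate 4, 592 without vehicle replicate 1, 643 without 5 mg/kg replicate 2, 592 without 5 mg/kg replicate 3, 202 with 1 probe set per gene fitted and adjusted alone, and 1673 with array weights.

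**Figure D2:**
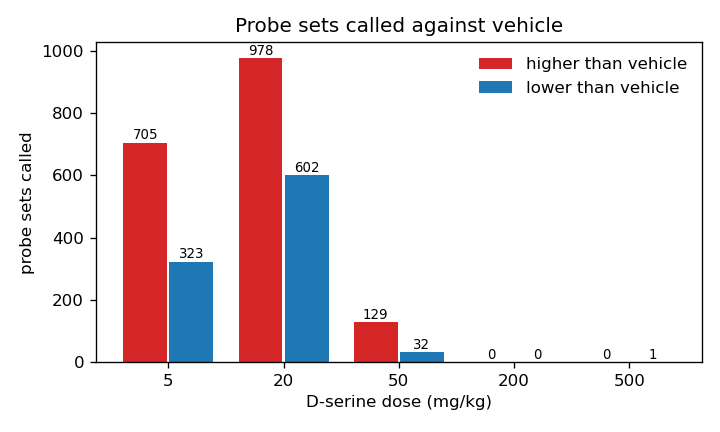
Number of probe sets that passed the limma test against vehicle (vertical axis) at each D-serine dose in mg/kg, split into higher (red) and lower (blue). The bars show 705 higher and 323 lower at 5 mg/kg, 978 and 602 at 20 mg/kg, 129 and 32 at 50 mg/kg, 0 at 200 mg/kg and 1 lower at 500 mg/kg.

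Among the fixed gene lists, 2 of energy metabolism passed camera at 5 mg/kg with medians above vehicle. Of 22 measured oxidative phosphorylation genes 18 lay above vehicle, with a median of 0.13, and 3 rose, namely the ATP synthase genes Atp5pb (0.37 ± 0.08, SE, n = 4) and Atp5f1a (0.38 ± 0.09) and the succinate dehydrogenase gene Sdha (0.28 ± 0.06). Adjusted over the list alone, 11 rose and 2 fell. The list passed camera, limma's test of a list against the other genes, with adjusted p = 0.000117, and did not with adjusted p = 0.4 with an estimated correlation. Of 14 glycolysis genes 13 lay above vehicle with a median of 0.16. Tpi1 rose by 0.36 ± 0.09 and Eno1 by 0.31 ± 0.09 (-0.034 and -0.027 with the Gapdh ratio as a covariate). Adjusted over the list alone 4 rose and 1, the neuronal enolase Eno2, fell by 0.26 (camera adjusted p = 0.00466, adjusted p = 0.271 with an estimated correlation). Without 5 mg/kg replicate 1 the glycolysis list had camera adjusted p = 0.0641. By fry, limma's test of members moving one way, adjusted p = 0.0251 for oxidative phosphorylation and 0.0124 for glycolysis. Both medians were above vehicle in a group with lower 3' to 5' ratios. In each comparison with vehicle, some other splits of the same arrays into groups of equal size gave more called lists than the real groups. The other splits had a median of 7, 6, 6, 6 and 5.5 called lists at 5, 20, 50, 200 and 500 mg/kg. The real groups had 4, 4, 5, 5 and 7.

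The myelin and reactive astrocyte lists passed camera at 5 mg/kg with medians below vehicle. Of 13 myelinating oligodendrocyte markers 12 lay below vehicle with a median of -0.38, although 0 passed singly in limma over all genes and 0 adjusted over the list alone. Mobp, a myelin protein gene, read -0.63 ± 0.22 (SE, n = 4, limma adjusted p = 0.106) and Fa2h, which makes hydroxylated myelin lipids, -0.61 ± 0.23 (adjusted p = 0.14). The list had camera adjusted p = 0.0139 and adjusted p = 0.705 with an estimated correlation, and without vehicle replicate 2 camera gave adjusted p = 0.365 with a median of -0.20. Thalamic and choroid plexus markers had medians further from vehicle, -0.58 and -0.66 with 8 of 9 below vehicle in each, and did not pass (camera adjusted p = 0.0692 for both). All 5 measured reactive astrocyte genes lay below vehicle with a median of -0.38. Hspb1 fell, with its 5 mg/kg arrays at 5.77 to 6.22, about the mean of 5.98 under which probe sets were left out. Adjusted over the list alone the intermediate filament gene Vim also fell, at -0.59 ± 0.19. Camera gave the list adjusted p = 0.046, and adjusted p = 0.366 with an estimated correlation. That list passed in 18 of the 24 settings that left out 1 array, with its largest adjusted p of 0.0677 without 5 mg/kg replicate 3. Fry gave adjusted p = 0.0262 for it and adjusted p = 0.459 for the myelin list.

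At 20 mg/kg, many of the same transcripts stood furthest from vehicle. Syt1 rose by 1.58 ± 0.30 on the log2 scale (SE, n = 4, limma adjusted p = 0.00171), or 2.99-fold, Svop by 1.21 ± 0.16 (adjusted p = 8.86e-05), Tbr1 by 1.16 ± 0.25 (adjusted p = 0.00459) and Sh3gl2 by 1.12 ± 0.20 (adjusted p = 0.00118). Hipk2 fell by 1.18 ± 0.18 (adjusted p = 0.00035), Srrm2, a component of the splicing machinery, by 0.82 ± 0.11 (adjusted p = 9.7e-05), and Mgll, which breaks down an endocannabinoid, by 0.95 ± 0.19 (adjusted p = 0.00287). Further rises were Fscn1 at 1.14, Cyria at 1.13, Rasgrp1 at 1.10, Cnbd2 and Frrs1l, whose product takes part in AMPA receptor assembly, at 1.09, the GABA-A receptor subunit gene Gabra3 at 0.98, the adhesion gene Cntn1 at 0.96 and Necab1 at 0.96. Further falls were the extracellular matrix gene Tnc and Pnma8b, both between Hipk2 and Mgll in size, the lysophosphatidic acid receptor gene Lpar1 at -0.92, Rbm27 at -0.91, the collagen gene Col9a3 and the histone demethylase gene Kdm6b at -0.84, Pik3c2b at -0.82, Cit at -0.79 and Slc22a15 at -0.78.

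In total, 1580 probe sets differed from vehicle at 20 mg/kg in limma, 978 higher and 602 lower, or 270 genes higher and 257 lower. The share of higher calls was 61.9%, against 72.9% with median centring and 99.7% as deposited, and the deposited values moved the median of all probe sets by 0.37 at 20 mg/kg and by 0.19 at 5 mg/kg. With the Gapdh ratio as a covariate, 500 mg/kg replicate 4 again included, 0 passed in limma and 1198 had an unadjusted p under 0.05. Syt1 then read -0.36, Rasgrp1 -0.64, Cyria -0.55, Gabra3 -0.15, Necab1 -0.12 and Pik3c2b 0.06. The count was 984 without 20 mg/kg replicate 2, 985 without 20 mg/kg replicate 3, 1031 without vehicle replicate 1, 2355 without 500 mg/kg replicate 4, 378 with 1 probe set per gene, 2432 with array weights and 6910 as deposited. Between 5 and 20 mg/kg, 616 higher and 250 lower calls were shared and 0 were opposite in limma, where independent lists of these sizes would share 37.0 and 10.4. Simulations with no effect against common vehicle arrays shared at most 0, which is no measure for this overlap, since without an effect few probe sets are called. With each dose set against a different 2 vehicle arrays, 162 to 224 higher and 14 to 40 lower calls were shared, where independent lists would share at most 10.1 and 2.34. The log2 changes at these doses correlated across probe sets, which are not independent replicates, at r = 0.87. Simulations with no effect against common vehicle arrays gave 0.50. With each dose set against other vehicle arrays, r was 0.49 to 0.62. The simulated 0.50 comes from the common arrays and is no measure for these split values, for which no simulation was run. Against common vehicle arrays the covariance of the changes was 0.0617 against 0.0165 simulated. A direct comparison of 5 with 20 mg/kg, chosen after the data were seen, gave 0 probe sets in limma and 397 at an unadjusted p under 0.05.

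**Figure D3:**
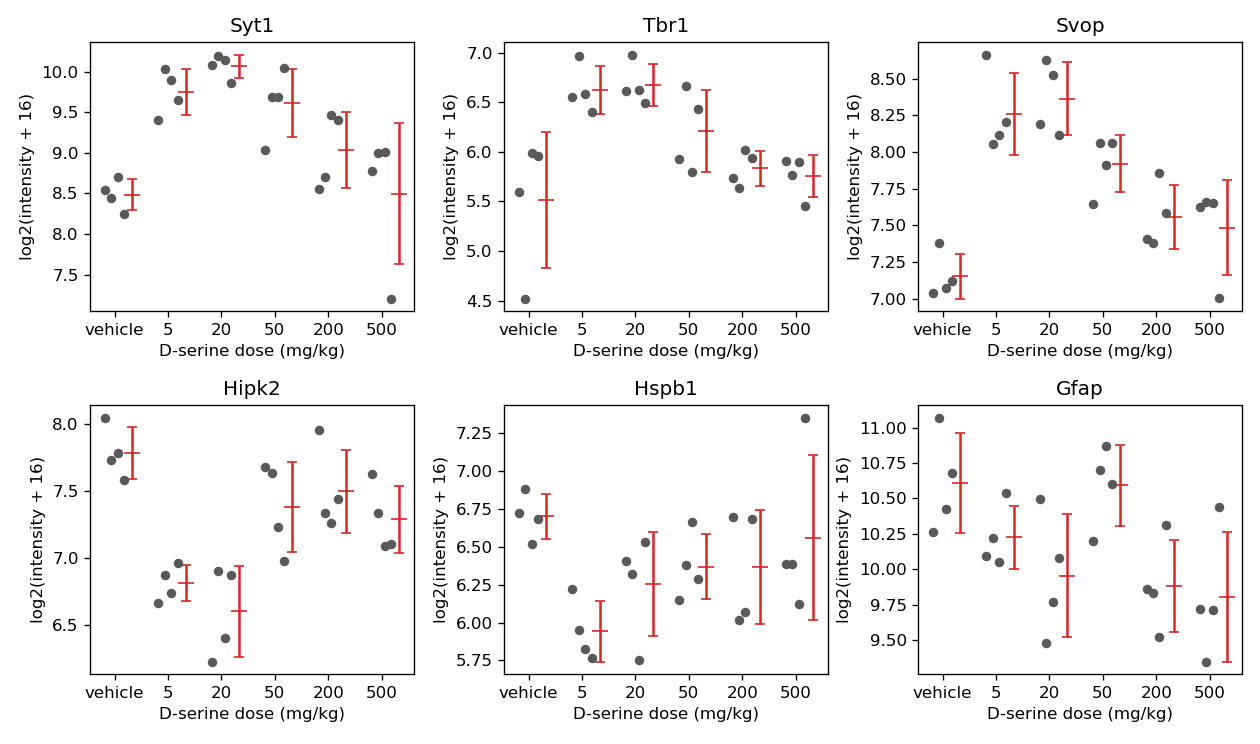
Expression as log2(intensity + 16) after quantile normalization against D-serine dose in mg/kg for Syt1, Tbr1, Svop, Hipk2, Hspb1 and Gfap; points are single arrays, and horizontal marks with bars are the mean ± SD of 4 arrays. Syt1, Tbr1 and Svop are higher and Hipk2 is lower on every 5 and 20 mg/kg array than on every vehicle array, while Gfap overlaps.

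The oxidative phosphorylation, glycolysis and myelin lists, which passed camera at 5 mg/kg, also passed at 20 mg/kg in the same direction. The reactive astrocyte list did not, with a median of -0.40 and 3 of 5 below vehicle (camera adjusted p = 0.285). Oxidative phosphorylation genes had a median of 0.16 with 17 of 22 above vehicle. Atp5pb (0.37 ± 0.08, SE, n = 4), Sdha (0.28 ± 0.06), Uqcrc2 (0.28 ± 0.08) and Atp5f1a (0.30 ± 0.09) rose. With p adjusted over the list alone 7 rose and 1, Ndufb3, fell (camera adjusted p = 0.00262, adjusted p = 0.576 with an estimated correlation). Glycolysis genes had a median of 0.16 with 12 of 14 above vehicle. Tpi1 rose by 0.48 ± 0.09 and Pgam1 by 0.27 ± 0.08, and 4 rose adjusted over the list alone (camera adjusted p = 0.00263, adjusted p = 0.251 with an estimated correlation). Myelinating oligodendrocyte markers had a median of -0.49 with 12 of 13 below vehicle and 0 past the limma test singly, over all genes or adjusted over the list alone. Opalin read -0.93 ± 0.37 and Cnp -0.61 ± 0.24 (camera adjusted p = 0.00262, adjusted p = 0.68 with an estimated correlation; adjusted p = 0.146 without vehicle replicate 2). All 9 thalamic neuron markers lay below vehicle with a median of -0.52, again with 0 past the limma test singly or adjusted over the list alone. Slc17a6, a vesicular glutamate transporter, read -1.29 ± 0.61 and the transcription factor gene Tcf7l2 -0.96 ± 0.54 (camera adjusted p = 0.0487, adjusted p = 0.68 with an estimated correlation). Without vehicle replicate 2, which had the highest thalamic marker level of the 24 arrays, the thalamic median was -0.18 and camera gave adjusted p = 0.505. The thalamic call held in 9 of 24 settings that left out 1 array. All 9 choroid plexus markers also lay below vehicle, with a median of -0.76, and this list did not pass (camera adjusted p = 0.0689). Fry gave adjusted p = 0.00548 for glycolysis, 0.0628 for oxidative phosphorylation and 0.3 for the myelin and thalamic lists.

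At 50 mg/kg fewer transcripts passed. Fscn1 rose by 0.85 ± 0.19 (SE, n = 4, limma adjusted p = 0.0321) and Svop by 0.77 ± 0.16 (adjusted p = 0.0248), Arl1, a GTPase of the Golgi, by 0.67 ± 0.09 (adjusted p = 0.00312), and Dnm1l, the GTPase of mitochondrial fission, by 0.53 ± 0.09 (adjusted p = 0.00874). Falls were led by Myl9, a smooth muscle myosin light chain, at -0.71 ± 0.16 (adjusted p = 0.0371), followed by Fbxo15 at -0.65 ± 0.12 (adjusted p = 0.0146). Other rises were Actr2-ps1 at 0.71, Tpgs1 and the phosphatase gene Ppm1a at 0.65, Vkorc1, the target of warfarin, at 0.62, Septin11 at 0.61, Faim2 at 0.58, Ddx3x-ps1 at 0.56 and the membrane protease gene Adam10 at 0.55. Other falls were the translation kinase gene Eef2k at -0.62, Acads, Ccdc62 and Rrbp1 at -0.58, Fbxl20 at -0.57, the actin cross-linker gene Flna at -0.55, Snrpd1 at -0.53, Cc2d2a and the lysosomal gene Lamp2 at -0.50 and Olfml2a at -0.47.

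In limma 161 probe sets passed at 50 mg/kg, 129 higher and 32 lower, or 23 genes higher and 18 lower, and 2410 had an unadjusted p under 0.05. The count was 0 with the Gapdh ratio as a covariate (1164 unadjusted), 18 without 50 mg/kg replicate 4, 48 without 50 mg/kg replicate 2, 57 without 50 mg/kg replicate 3, 60 without vehicle replicate 1, 68 without vehicle replicate 4, 406 without 50 mg/kg replicate 1 and 452 without 500 mg/kg replicate 4. The higher share was 80.1%, against 100% with the values as deposited. Of these calls, 125 higher and 22 lower were shared with 5 mg/kg and 128 and 25 with 20 mg/kg, where independent lists would share 4.88 and 0.555, and 6.77 and 1.03. With a different 2 vehicle arrays for each dose, 0 to 35 higher and 0 to 1 lower calls in limma were shared with 5 mg/kg and 1 to 40 and 0 to 2 with 20 mg/kg. In these settings only 2 to 82 probe sets passed at 50 mg/kg. Independent lists would share at most 0.957 higher calls with 5 mg/kg and 1.51 with 20 mg/kg. The shared counts fell along with the calls, so they do not decide whether part of the overlap comes from the common vehicle arrays.

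At 50 mg/kg 5 lists passed camera, with 0 members past the limma test over all genes. Of 15 meningeal fibroblast and matrix genes 14 lay below vehicle with a median of -0.40, and 0 passed in limma over all genes. With p adjusted over the list alone 2 fell, Slc13a3 at -0.71 ± 0.20 (SE, n = 4) and the collagen gene Col3a1 at -0.89 ± 0.25 (camera adjusted p = 5.21e-06, adjusted p = 0.516 with an estimated correlation). Of 14 striatal projection neuron markers 13 lay below vehicle with a median of -0.76 and 0 passed in limma over all genes or adjusted over the list alone. The dopamine receptor gene Drd2 read -1.14 ± 0.63 and the opioid peptide gene Penk -1.11 ± 0.64 (camera adjusted p = 0.0035, adjusted p = 0.939 with an estimated correlation). Leaving out 1 array, the striatal median ran from -1.30 to -0.39. The latter was without vehicle replicate 4, where camera gave adjusted p = 0.238. Excitatory cortical and hippocampal neuron markers had a median of 0.46 with 11 of 13 above vehicle, such as Tbr1 at 0.69 ± 0.25 (camera adjusted p = 0.0166, adjusted p = 0.608 with an estimated correlation). Without vehicle replicate 4 the excitatory median was 0.27 and camera gave adjusted p = 0.148. Endothelial markers had a median of -0.17 with 11 of 12 below vehicle, such as the transporter gene Slco1a4 at -0.37 ± 0.13 (camera adjusted p = 0.0166, adjusted p = 0.608 with an estimated correlation). Without vehicle replicate 1 the endothelial median was -0.058 and camera gave adjusted p = 0.359. Neither of these lists had a member past the limma test over all genes or adjusted over the list alone. Oxidative phosphorylation genes had a median of 0.11 with 16 of 22 above vehicle. Of these 0 passed in limma over all genes and 4 rose adjusted over the list alone, namely Atp5pb, Sdha, Atp5f1a and Ndufa4 (camera adjusted p = 0.000754, adjusted p = 0.516 with an estimated correlation). Fry adjusted p values of these 5 lists ran from 0.221 to 0.751.

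**Figure D4:**
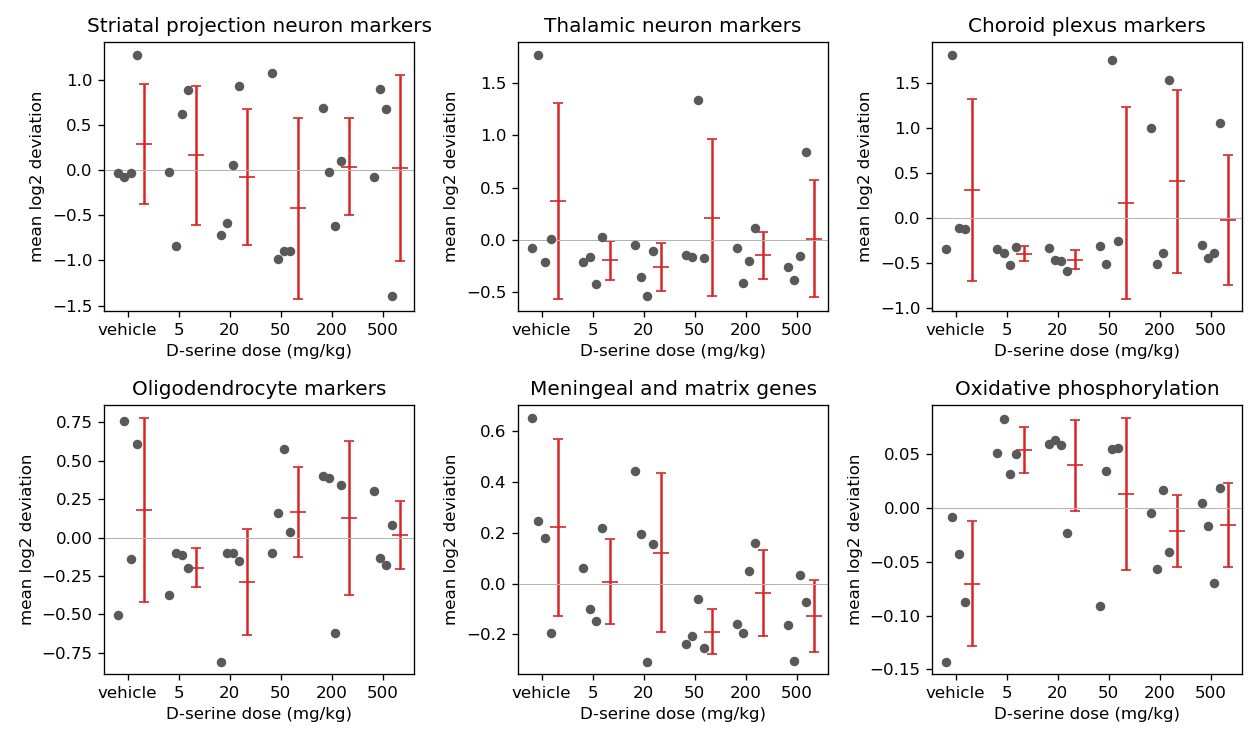
Mean log2 deviation of the members of 6 gene lists from their mean over all arrays, against D-serine dose in mg/kg; points are single arrays, and horizontal marks with bars are the mean ± SD of 4 arrays. Single arrays reach 1.77 in thalamic markers and 1.82 in choroid plexus markers (both vehicle replicate 2) and 1.28 in striatal markers (vehicle replicate 4).

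At 200 mg/kg no transcript passed the test: limma called 0 of 18625 probe sets, and 987 had an unadjusted p under 0.05 where chance gives about 931. The smallest p values belonged to Xiap, an inhibitor of caspases, at -0.40 ± 0.08 (SE, n = 4, limma adjusted p = 0.665), LOC100911253 at -0.44 ± 0.10 and Olfml2a at -0.47 ± 0.11 (both adjusted p = 0.667). Hist3h2ba read 0.43, Dnm1l 0.36, Fscn1 0.73, Mpst -0.39, Setd5 -0.41, Ppm1a 0.55 and the myosin light chain kinase gene Mylk -0.35, none of them past the threshold. Leaving out 200 mg/kg replicate 4 gave 7 probe sets.

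At 200 mg/kg 5 lists of genes passed camera, with 0 members past the limma test over all genes. Of 15 meningeal fibroblast and matrix genes 14 lay below vehicle with a median of -0.22, such as Col3a1 at -0.70 ± 0.25 (SE, n = 4; camera adjusted p = 0.000404, adjusted p = 0.591 with an estimated correlation). All 9 thalamic neuron markers lay below with a median of -0.48, such as Lef1 at -0.54 ± 0.23 (camera adjusted p = 0.00528, adjusted p = 0.668 with an estimated correlation). Of 12 endothelial markers 9 lay below with a median of -0.19, such as Esam, a junction protein gene, at -0.29 ± 0.13 (camera adjusted p = 0.00569, adjusted p = 0.591 with an estimated correlation). Glycolysis genes had a median of 0.11 with 12 of 14 above, such as Tpi1 at 0.19 ± 0.09 (camera adjusted p = 0.011, adjusted p = 0.414 with an estimated correlation). Reactive astrocyte genes had a median of -0.33 with 4 of 5 below. Adjusted over the list alone 1 fell, Gfap, at -0.73 ± 0.23 (camera adjusted p = 0.0449, adjusted p = 0.414 with an estimated correlation). Adjusted over the list alone the other 4 lists had 0 members past the limma test. The reactive astrocyte call held in 15 of 24 settings that left out 1 array, and the glycolysis list had adjusted p = 0.0653 without vehicle replicate 4. Without vehicle replicate 2 the thalamic median was -0.05 with camera adjusted p = 0.639, and without vehicle replicate 1 camera gave adjusted p = 0.152 for the meningeal and adjusted p = 0.276 for the endothelial list. Fry adjusted p values of the 5 lists ran from 0.651 to 0.795.

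At 500 mg/kg, the highest dose, 1 probe set passed in limma. It belonged to Sptbn1, a spectrin of the membrane skeleton, and fell by 0.58 (limma adjusted p = 0.00758). It is named after its value was seen and is not the probe set that stands for this gene in the gene counts. At an unadjusted p under 0.05 there were 1285 probe sets. In limma 0 passed without vehicle replicate 1 or without vehicle replicate 2, 2 without vehicle replicate 3 and 3 without vehicle replicate 4. Among genes taken at 1 probe set each, limma called 0. The smallest p values belonged to Sox17, an endothelial transcription factor, at -0.74 ± 0.14 (SE, n = 4, limma adjusted p = 0.143), and to Olfml2a at -0.54 ± 0.11 and Elk3 at -0.56 ± 0.12 (both adjusted p = 0.169). Others not past the threshold were Ubap2l at 0.56, Hist3h2ba at 0.50, Oxnad1 at 0.55, Morc3 at 0.41, the prolactin receptor gene Prlr at -0.64, Map7d2 at -0.42 and Xiap at -0.36. The log2 changes at 200 and 500 mg/kg correlated across probe sets at r = 0.42, below the 0.50 of simulations with no effect against common vehicle arrays, and at -0.12 to 0.09 against other vehicle arrays. Their covariance was 0.0141 against 0.0164 simulated. The 500 mg/kg mean included replicate 4, which stood apart, while the simulations held no such array. No correlation was computed without it, so these values do not decide whether both doses share a change.

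At 500 mg/kg 7 lists passed camera, again with 0 members past the limma test over all genes. Endothelial markers had a median of -0.26 with 11 of 12 below vehicle. With p adjusted over the list alone 2 fell, Slco1a4 at -0.48 ± 0.13 (SE, n = 4) and Esam at -0.41 ± 0.13 (camera adjusted p = 1.7e-05, adjusted p = 0.171 with an estimated correlation). All 15 meningeal fibroblast and matrix genes lay below with a median of -0.30, and Col3a1, at -0.96 ± 0.25, fell adjusted over the list alone (camera adjusted p = 1.72e-05, adjusted p = 0.492 with an estimated correlation). Glucocorticoid-responsive genes had a median of 0.19 with 12 of 14 above, and Sgk1, a kinase induced by corticosteroids, rose by 0.96 ± 0.28 adjusted over the list alone (camera adjusted p = 0.00512, adjusted p = 0.655 with an estimated correlation). All 5 reactive astrocyte genes lay below with a median of -0.25. Of these 2 fell adjusted over the list alone, Gfap, the filament protein of astrocytes, at -0.81 ± 0.23 and Vim at -0.59 ± 0.19 (camera adjusted p = 0.0153, adjusted p = 0.171 with an estimated correlation). Of 9 interferon-induced genes 8 lay below with a median of -0.24, such as Isg15 at -0.71 ± 0.26 (camera adjusted p = 0.022, adjusted p = 0.171 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.05 with 17 of 22 above (camera adjusted p = 0.031, adjusted p = 0.655 with an estimated correlation), and with the values as deposited their median was -0.02 (camera adjusted p = 0.156). All 9 choroid plexus markers lay below with a median of -0.34, and Prlr fell adjusted over the list alone (camera adjusted p = 0.0328, adjusted p = 0.655 with an estimated correlation). Without vehicle replicate 2 this median was 0.11 and camera gave adjusted p = 0.754, and with the values as deposited camera gave adjusted p = 0.0668. The interferon and oxidative phosphorylation lists had 0 members past the limma test adjusted over the list alone. Camera gave adjusted p = 0.188 for oxidative phosphorylation without vehicle replicate 1 and adjusted p = 0.0967 for the reactive astrocyte list without 500 mg/kg replicate 1. Without vehicle replicate 3 the interferon median was -0.10 and camera gave adjusted p = 0.141. Fry adjusted p values of the 7 lists ran from 0.0918 to 0.565. Leaving out 1 array, the meningeal median ran from -0.42 to -0.18, the reactive astrocyte median from -0.46 to -0.08 and the glucocorticoid median from 0.08 to 0.27. Without 500 mg/kg replicate 4, the reactive astrocyte median was -0.40 (camera adjusted p = 0.00772 with an estimated correlation, fry adjusted p = 0.00285). The choroid plexus median was then -0.62, while the glucocorticoid median was 0.13 with camera adjusted p = 0.049. Without that array oxidative phosphorylation did not pass (median 0.02, camera adjusted p = 0.0948). Thalamic (median -0.69, camera adjusted p = 0.000175), GABAergic interneuron (0.23, adjusted p = 0.0354), glycolysis (0.06) and pericyte lists (-0.08, both adjusted p = 0.0305) then passed camera, though none of these 4 with an estimated correlation (adjusted p of 0.338 to 0.37).

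Across all doses, 1105 probe sets differed among the 6 groups in the limma F test, of which 344 were counted as genes at 1 probe set each, and 0 passed with the Gapdh ratio as a covariate (776 unadjusted). A steady rise or fall over the 6 ranked doses was not detected: limma called 0 probe sets, with 1067 at an unadjusted p under 0.05. The smallest p values of a slope belonged to Olfml2a and to Tm4sf1, a membrane protein of vessels, both at -0.10 ± 0.02 log2 units per dose step (SE, limma adjusted p = 0.159). Sox17 at -0.11, Elk3 at -0.09, Tmem176b at -0.10, Col3a1 at -0.17, Serpinh1 at -0.09, Ddx42 at 0.05, Rnf6 at 0.08 and Morc3 at 0.07 followed, none past the threshold. Over the 5 treated groups alone 1914 probe sets had a slope, 766 up and 1148 down, and these 5 groups run from lower to higher 3' to 5' ratios.

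By camera 5 lists had a slope, with 0 members past the limma test over all genes. Meningeal fibroblast and matrix genes had a median slope of -0.05 with 14 of 15 below 0 and 1, Col3a1, falling adjusted over the list alone (camera adjusted p = 2.57e-06, adjusted p = 0.309 with an estimated correlation). Leaving out 1 array, the meningeal median slope ran from -0.076 to -0.032. Endothelial markers had a median slope of -0.04 with 11 of 12 below 0, and Esam, Slco1a4 and the tight junction gene Cldn5 fell adjusted over the list alone (camera adjusted p = 2.88e-05, adjusted p = 0.272 with an estimated correlation). Glucocorticoid-responsive genes had a median slope of 0.03 with 13 of 14 above 0, and Sgk1 rose by 0.16 ± 0.05 per step adjusted over the list alone (camera adjusted p = 0.00409, adjusted p = 0.466 with an estimated correlation). With the values as deposited their median slope was -0.01. NRF2 and antioxidant genes had a median slope of -0.02 with 12 of 14 below 0, such as the cystine transporter gene Slc7a11 at -0.08 ± 0.03 (camera adjusted p = 0.0103, adjusted p = 0.309 with an estimated correlation). Interferon-induced genes had a median slope of -0.04 with 8 of 9 below 0, such as Isg15 at -0.10 ± 0.04 (camera adjusted p = 0.0304, adjusted p = 0.272 with an estimated correlation; adjusted p = 0.211 without vehicle replicate 3). The last 2 lists had 0 members past the limma test adjusted over the list alone. Fry adjusted p values of the 5 lists ran from 0.23 to 0.432.

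Set directly against each other, 500 and 200 mg/kg did not differ detectably: limma called 0 probe sets, with 969 at an unadjusted p under 0.05, and camera called 0 lists. The smallest p values belonged to Slc23a2, a vitamin C transporter gene, at -0.50 ± 0.12 (SE, n = 4, limma adjusted p = 0.808), Cxhxorf38 at 0.45 ± 0.11 and Col22a1 at 0.44 ± 0.11. Fam193a at 0.29, Dkc1 at 0.41, the Wnt receptor gene Fzd2 at -0.54, Smim8 at 0.42, the kainate receptor gene Grik4 at -0.64, Sox17 at -0.49 and Cygb at 0.36 had the same adjusted p. The excitatory neuron markers had a median of -0.41, the synaptic vesicle genes -0.15 (camera adjusted p = 0.0574 for both) and the glucocorticoid-responsive genes 0.17 (camera adjusted p = 0.0585). Without 500 mg/kg replicate 4 these medians were -0.046 (camera adjusted p = 0.672), -0.051 (adjusted p = 0.567) and 0.12 (adjusted p = 0.323), and striatal (0.43, adjusted p = 0.0196) and choroid plexus markers (-0.38, adjusted p = 0.000911) passed camera, both with adjusted p = 0.909 with an estimated correlation.

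The genes of D-serine handling and NMDA receptors that were named singly beforehand did not pass at any dose. The transporter gene Slc7a10 read -0.29, -0.16, -0.10, -0.04 and 0.12 at 5, 20, 50, 200 and 500 mg/kg with an SE of 0.15, Slc1a4 read -0.08, 0.02, 0.15, -0.07 and 0.07 with an SE of 0.22, and the glycine transporter gene Slc6a9 read -0.27, -0.46, -0.14, -0.18 and -0.10 with an SE of 0.25. The receptor subunit gene Grin1 read 0.11, -0.02, -0.13, -0.09 and -0.07 with an SE of 0.11, while with the values as deposited it read 0.43 at 20 mg/kg. Grin2a read -0.57, -0.40, -0.24, -0.17 and -0.46 with an SE of 0.20 (smallest limma adjusted p = 0.112, at 5 mg/kg), and Grin2b read 0.14, 0.29, 0.21, 0.13 and -0.36 with an SE of 0.26. Of the activity-regulated genes, Fos read 0.00, -0.61, 0.29, -0.04 and -0.10 (SE 0.37), Arc -0.23, -0.56, 0.02, -0.44 and -0.42 (SE 0.31) and Egr1 0.16, -0.34, -0.06, 0.10 and -0.36 (SE 0.35). Gfap read -0.38, -0.66, -0.02, -0.73 and -0.81 (SE 0.23, smallest adjusted p = 0.0835, at 20 mg/kg), and the microglial gene Aif1 -0.06, -0.14, -0.19, -0.27 and -0.40 (SE 0.19). Without 500 mg/kg replicate 4, the 500 mg/kg values were 0.05 for Slc7a10, 0.22 for Slc1a4, -0.36 for Slc6a9, -0.12 for Grin1, -0.18 for Grin2a, 0.09 for Grin2b, 0.33 for Fos, 0.03 for Arc, 0.24 for Egr1, -1.02 for Gfap, -0.18 for Aif1, -0.02 for Mbp, -1.01 for Hbb and -1.60 for Ttr (-0.16 with all arrays). The myelin gene Mbp read -0.11, -0.16, -0.04, -0.04 and 0.02 (SE 0.08), while 1 of its other probe sets was lower at 5 and at 20 mg/kg. The haemoglobin gene Hbb read -1.30 ± 0.41 at 200 mg/kg (SE, n = 4, limma adjusted p = 0.756), and Ttr, a product of the choroid plexus, had an SE of 1.68. Srr, the gene of the enzyme that makes D-serine, had 0 probe sets named by it alone, and Dao and Lcn2 lay below the signal filter.

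Within lists that did not pass as a whole, single members did. Dlg2, a scaffold of the postsynaptic density, rose by 0.64 ± 0.15 at 5 mg/kg (SE, n = 4, limma adjusted p = 0.0119) and by 0.82 ± 0.15 at 20 mg/kg (adjusted p = 0.00122), while Camk2b fell by 0.22 ± 0.06 and 0.21 ± 0.06 but read 0.06 and 0.24 with the values as deposited. In both comparisons these were the members of the NMDA receptor and postsynaptic density list that passed, over all genes and adjusted over the list alone. Grm7, a presynaptic glutamate receptor gene, rose by 0.63 ± 0.18 and 0.78 ± 0.18 but read -0.29 and -0.15 with the Gapdh ratio as a covariate, and Cplx2, a complexin of vesicle release, fell by 0.51 ± 0.11 at 5 mg/kg. Pick1, from the D-serine and glycine handling list, fell by 0.54 ± 0.17 at 20 mg/kg (adjusted p = 0.0468), where 1 of 13 members passed over all genes and 1 adjusted over the list alone. These 5 genes were chosen after their values were seen.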

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

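Chosen only after the result was seen were the tests on brightness, on a growing effect and on an effect lost at higher doses, both tests on region markers, and every comparison with other splits of the arrays; the tests on RNA length, on cerebellar tissue and on an effect of 500 mg/kg on its markers were fixed beforehand, although the positions of the 200 mg/kg arrays on the second principal component had been seen.

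Of 5 array measures in the 6 groups, 2 set an array apart from the other 3 of its group: the median correlation of 500 mg/kg replicate 4 with the other arrays, 0.855, and the median intensity of 50 mg/kg replicate 3, 78.9. Of 167 named genes, an array lay apart from the other 3 of its group in 12 genes in vehicle, 7 at 5 mg/kg, 7 at 20 mg/kg, 15 at 50 mg/kg, 10 at 200 mg/kg and 20 at 500 mg/kg, where 16 of the 20 were on replicate 4. Of 36 list scores the numbers were 3 in vehicle, 2 at 20 mg/kg, 9 at 50 mg/kg, 2 at 200 mg/kg and 4 at 500 mg/kg. Chance marks about 1 in 20 groups of 4 in this way. On vehicle replicate 2 the choroid plexus score was 1.82 and the thalamic score 1.77, on 50 mg/kg replicate 3 they were 1.76 and 1.34, and the striatal score was 1.28 on vehicle replicate 4 and 1.07 on 50 mg/kg replicate 1.

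In limma 1028 and 1580 probe sets passed at 5 and 20 mg/kg and 0 at 200 mg/kg (987 unadjusted), and a candidate explanation is a difference in RNA length or labelling between arrays. Across the 1742 probe sets that passed at either low dose, the change there correlated at r = 0.812 with the slope on the Gapdh 3' to 5' ratio, sign turned, within the 50, 200 and 500 mg/kg groups (11 arrays, without 500 mg/kg replicate 4); of 100 shuffles of the ratio within groups, the highest gave 0.815 and the share as high was 0.0198; across all tested probe sets r was 0.44, and single groups gave 0.58 at 50, 0.78 at 200 and 0.09 at 500 mg/kg. Array brightness was already equalized by the quantile normalization behind these counts. With arrays centred on their medians instead, 928 probe sets passed at 5 mg/kg, so this count cannot decide about brightness. Over the same 1742 probe sets the median change in the direction of the low doses was 0.0968 at 500 mg/kg (0.08 to 0.15 leaving out 1 array) against 0.31 at 50 mg/kg. These probe sets did not change more at the highest dose. They were chosen by their low-dose change, and the 50 mg/kg group also had lower 3' to 5' ratios. The medians therefore cannot decide about an effect that grows with dose. An effect of D-serine at 5 and 20 mg/kg that is lost at higher doses cannot be told apart from the RNA difference: with the Gapdh ratio as a covariate the median change at 20 mg/kg was 0.181 with a median SE of 0.22, against 0.51 with 0.13 without it. Ratio and dose group go together, which widens the error, and why the change was smaller was not tested. The covariate fit kept 500 mg/kg replicate 4, which the slope above left out. Order of handling is confounded with dose in the same way and was not tested.

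The array of 500 mg/kg replicate 4 stands apart in 422 probe sets by at least 2 log2 units from the other 3 arrays of its group, where no other array exceeded 15, and a candidate explanation is cerebellar tissue in the piece. Of 12 cerebellar markers not looked at before the test, of which 0 were in another fixed list, the median was 1.79 above the other 3 arrays, and 11 were higher than on each of the other 23 arrays, the exception being Zic2; Gabra6 was 5.80, Fat2 5.69 and En2 4.76 higher, and the highest median on any other array was 0.28. An effect of 500 mg/kg itself is argued against, since the same markers in replicates 1 to 3 were -0.157 from vehicle. A part played by RNA length stays open, since the array's deviation correlated with the low-dose change at r = -0.228, which is 5.21% of the variance. Forebrain genes such as Bcl11b (-4.79), Nrgn (-4.81) and Cck (-4.31) were far lower on it, while Neurod6 read -0.75.

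Striatal, thalamic, choroid plexus and meningeal lists were called in comparisons with vehicle, and a candidate explanation is that the pieces held brain regions and membranes in unequal amounts. Within groups, without 500 mg/kg replicate 4, the mean correlations between members were 0.87, 0.65, 0.66 and, the lowest, 0.417 for the meningeal list, against at most 0.17 in 100 random lists for each. This leaves unequal amounts open, since genes of a process also go together: ribosomal proteins had 0.48, above the meningeal list, cholesterol synthesis 0.38 and immediate-early genes 0.33. An effect of D-serine on these markers cannot be told apart with 4 rats per group: over the 6 groups the smallest adjusted permutation p of a list score was 0.589. The labels do not say how the pieces were dissected.

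Other splits of the same arrays into groups of the same size were set beside each count. The real groups gave the highest count at 5 mg/kg (1 of 35 splits as high, 1028 against at most 2), 20 mg/kg (1 of 35, 1580 against 2) and 50 mg/kg (1 of 35, 161 against 2). They also did in the F test (1 of 100, 1105 against 1) and for 20 against 500 (1 of 35, 1339 against 1) and against 200 mg/kg (1 of 35, 271 against 0). These are the smallest shares that 35 or 100 splits can give, and they were not adjusted over the comparisons. A random grouping of the arrays is thus an unlikely source of these counts, but chance is not excluded. The splits also do not separate dose from the 3' to 5' ratio. Chance cannot be excluded at 500 mg/kg (3 of 35, 1 against 1). Where the real count in limma was 0, every split is as high by definition and the comparison with other splits decides nothing: at 200 mg/kg (35 of 35, 0 against 2, with 987 unadjusted), for 500 against 200 mg/kg (35 of 35, 0 against 1 probe sets and 0 against 9 lists), for 20 against 5 mg/kg (35 of 35, 0 against 0, with 397 unadjusted) and for the slope (100 of 100, 0 against 243). The 243 came from 1 regrouping, which may follow some structure of the arrays that was not tested. For the other numbers of lists chance cannot be excluded: 27 of 35 splits gave as many at 5 mg/kg (4 against 14), 29 at 20 mg/kg (4 against 13), 22 at 50 mg/kg (5 against 12), 24 at 200 mg/kg (5 against 11), 16 at 500 mg/kg (7 against 13) and 35 of 100 for the slope (5 against 11).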

How the results depend on the processing

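The values as deposited, the Gapdh ratio as a covariate and median centring of the lists were tests chosen after the data were seen. Quantile normalization, listed as an alternative, is the setting used throughout. The causes of the changes below were not tested. At 5 and 20 mg/kg the counts of probe sets stayed within 1.5 times with no filter, the lowest 60% left out, median centring, other pseudocounts, other moderation and only the arrays compared. Array weights gave 1673, 2432, 720 and 2340 at 5, 20 and 50 mg/kg and in the F test. Testing 1 probe set per gene gave 202, 378, 16, 0 and 249 at 5, 20, 50 and 500 mg/kg and in the F test. At 50 mg/kg no filter gave 102, median centring 98 and the 8 arrays alone 55. At 500 mg/kg the last 2 gave 0 in limma. The values as deposited gave 6910 at 20, 56 at 50 and 0 at 500 mg/kg in limma and 5619 in the F test. The slope had 1 call with log10 dose, 1 with dose in mg/kg and 1914 in the treated groups alone. With the Gapdh ratio as a covariate limma gave 0 at 5, 20 and 50 mg/kg and in the F test and 1 for the slope.

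Leaving out 1 array gave 592 to 1668 probe sets at 5 mg/kg, 984 to 2355 at 20 mg/kg, 18 to 452 at 50 mg/kg, 0 to 7 at 200 mg/kg and 0 to 3 at 500 mg/kg. It gave 719 (without 20 mg/kg replicate 3) to 1393 in the F test and 0 for the slope and for 500 against 200 mg/kg throughout. For lists the ranges were 1 (without 5 mg/kg replicate 1) to 9 (without 5 mg/kg replicate 4) at 5 mg/kg, with 2 without vehicle replicate 2. At 20 mg/kg they were 2 (without vehicle replicate 2 or 20 mg/kg replicate 1) to 7 (without vehicle replicate 3 or 20 mg/kg replicate 4). At 50 mg/kg they were 2 (without 50 mg/kg replicate 2) to 7, with 3 without 50 mg/kg replicate 4 or vehicle replicate 4. At 200 mg/kg they were 3 (without vehicle replicate 2 or 4) to 7. At 500 mg/kg they were 4 (without 500 mg/kg replicate 1) to 10 (without 500 mg/kg replicate 4). For the slope they were 4 (without 500 mg/kg replicate 1) to 9 (without vehicle replicate 4), with 8 without 500 mg/kg replicate 3 or 4. For 500 against 200 mg/kg they were 0 to 4 (without 200 mg/kg replicate 3 or 500 mg/kg replicate 3), with 2 or 3 without the other 200 mg/kg arrays, 500 mg/kg replicates 1 and 4, vehicle replicate 1 and 5 mg/kg replicates 1 and 2.

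With all 24 arrays, camera with an estimated correlation called 0 lists at each dose and for the slope. Fry with all 24 arrays called 1 at 20 mg/kg and 0 at 50, 200 and 500 mg/kg and for the slope. Median centring gave 8, 7, 9 and 11 lists at 5, 20, 200 and 500 mg/kg and 9 for the slope. The values as deposited gave 10, 15 and 8 at 5, 20 and 200 mg/kg and 3 for 500 against 200 mg/kg, where no filter gave 4. Single genes turned direction under the Gapdh covariate, in a fit that kept 500 mg/kg replicate 4. At 5 mg/kg these were Syt1 (-0.64), Rasgrp1 (-0.50), Necab1 (-0.17), Pik3c2b (0.068), Tpi1 (-0.034), Eno1 (-0.027) and Grm7 (-0.29). At 20 mg/kg they were Syt1 (-0.36), Cyria (-0.55), Rasgrp1 (-0.64), Gabra3 (-0.15), Necab1 (-0.12), Pik3c2b (0.055) and Grm7 (-0.15). With the values as deposited they were Grin1 at 20 mg/kg (0.43) and Camk2b at 5 (0.059) and 20 mg/kg (0.24). Of 334 values of named genes 91 had a call. With the covariate all 91 lost it, 14 of them with a turned direction, and with the values as deposited 39 lost it in the same direction. Robust moderation changed 0 calls among the named genes.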

Other observations

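All comparisons between dose groups other than 500 against 200 mg/kg were tests chosen after the data were seen, as were the single genes named here.

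Several gene groups of interest for a glutamate receptor agonist did not stand apart from the other genes in any comparison of all 24 arrays. The smallest camera adjusted p of the immediate-early genes was 0.0799, at 500 mg/kg with a median of -0.19, and that of the NMDA receptor and postsynaptic density list was also 0.0799, at 500 mg/kg with a median of -0.11. Without 500 mg/kg replicate 4 these medians were 0.12 (camera adjusted p = 0.545) and -0.0051 (adjusted p = 0.856). AMPA, kainate and metabotropic receptor genes reached 0.376 (500 against 200 mg/kg, median -0.18, or -0.023 with adjusted p = 0.672 without that array). D-serine and glycine handling reached 0.234 (20 mg/kg, median -0.15) and urea and ammonia linked genes 0.175 (50 mg/kg, median 0.12). At 20 mg/kg without 500 mg/kg replicate 4, fry gave adjusted p = 0.0211 for the D-serine and 0.0441 for the urea list. Camera then gave adjusted p = 0.177 and 0.269. Fry with all 24 arrays gave adjusted p = 0.0858 and 0.104. Microglia and macrophage markers reached 0.0689 in the slope over dose, with a median of -0.025 per step, or -0.0052 with adjusted p = 0.412 without 500 mg/kg replicate 4. At 20 mg/kg their members C1qb and Cx3cr1 read 0.52 and 0.39, and both rose adjusted over the list alone and not over all genes. Inflammatory genes reached 0.345 and astrocyte markers 0.621. GABAergic interneuron markers reached 0.423, hypoxia-induced genes 0.265, heat shock genes 0.472 and p53 and apoptosis genes 0.565. At 500 mg/kg the GABAergic median was -0.14, but 0.23 without replicate 4, where camera gave adjusted p = 0.0354 and adjusted p = 0.37 with an estimated correlation.

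The red blood cell list had too few measured members for a test. At 200 mg/kg Hbb read -1.30 and Alas2 -1.07, and both fell adjusted over the list alone (limma adjusted p = 0.0103 for both, against 0.756 and 0.811 over all genes). At 500 mg/kg they read -1.14 and -0.97, and 2 of the 3 measured members of the list fell adjusted over the list alone. In the slope over dose 2 of the 3 also fell adjusted in this way. At 50 mg/kg the hypothalamic peptide genes Nts and Pmch read 1.52 and -1.20, past the test adjusted over the list alone and not over all genes. Of the vessel wall genes at 5 mg/kg, Kcnj8 and Rgs5 read 0.50 and 0.38 and Myl9 -0.51, all 3 past the test adjusted over the list alone and not over all genes. Myl9 also fell adjusted over the list alone at 50 (-0.71) and 200 mg/kg (-0.49), and Myh11 at 50 mg/kg (-0.46). At 20 mg/kg Rgs5 rose by 0.56 (limma adjusted p = 0.00849 over all genes).

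Direct comparisons of dose groups gave most of their calls between groups of lower and of higher 3' to 5' ratio. These groups also differ in dose, and whether the counts follow the ratios was not tested. In limma 20 differed from 500 mg/kg in 1339 probe sets and 5 from 500 mg/kg in 739, and without 500 mg/kg replicate 4 in 658 and 354. From 200 mg/kg, 20 differed in 271 and 5 in 119, and without that array in 572 and 291. Between 50 and 500 mg/kg there were 59, or 13 without it. Of the 6 pairs of groups with beta-actin ratios on the same side, 1 had a call, and of the 9 other pairs 8 had calls. Without 500 mg/kg replicate 4 these numbers were 2 and 9. Sorted by the animal numbers in the labels, the groups' mean Gapdh ratios were 0.83 in vehicle, 0.75 at 500, 0.60 at 200, 0.34 at 50, 0.18 at 20 and 0.19 at 5 mg/kg. No test was made of that order.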
